A study of Rattus norvegicus with 9 samples.

How the data were processed

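The data are RNA-seq read counts of RN46A cells in 3 groups of 3 libraries (control, lithium, VPA), grouped and numbered by the submitters' titles. Polyadenylated RNA with a RIN above 7 was sequenced unstranded, per the labels' protocols, so reads of a gene and of an overlapping or antisense neighbour cannot be told apart. CASAVA 1.8, STAR 2.5.1, kallisto 0.42.4, Salmon 0.6.1, Cufflinks 2.2.1, DESeq2 and sleuth are named in the submitters' processing notes, without roles. Genome build and annotation are not given in the sources used here. Positions are therefore printed only as the authors' table gives them, and whether its starts count from 0 or from 1 is not given either.

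The authors deposited a table of raw counts per Ensembl gene, whole numbers that sum to 9580591 to 13030300 per library, with 0 lines that name no gene; HTSeq and STAR as its source are per the table's title and the submitters' processing notes. The authors deposited a DESeq2 table for VPA with log2 fold changes, their standard errors, mean normalized counts (a signal), a test score and p-values, per the file headers, listing 1212 genes up to an adjusted p of 0.05. A table titled for kallisto and sleuth repeats it in all 1212 lines and was not used. The authors' Cufflinks table gives 1 FPKM value per group and log2 ratios of control over VPA, per the file headers, which were turned to VPA over control here. The authors' Salmon and sleuth table gives effects per transcript on a natural log scale, as the median ratio of 0.697 to the Cufflinks log2 values over 586 transcripts shows. The authors' lithium table gives log2 values, p-values and normalized counts (a signal), per the file headers. The highest unadjusted p from DESeq2 in it is 0.0499, so a limit of 0.05 was inferred from its values. Its reads per lithium library exceeded those of the count table by 4.87, 5.99 and 6.25% over the same genes. It therefore comes from another counting. The deposited q-values and adjusted p-values are the authors' own.

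Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3: TMM factors, filterByExpr (minimum count 10), a robust quasi-likelihood fit of group means over all 9 libraries (6 residual degrees of freedom), two-sided tests and Benjamini-Hochberg adjustment over the 12719 genes kept. A gene was called at an adjusted p under 0.05, and the standard error of a log2 fold change was its size over the square root of F. CPM used TMM-scaled library sizes, and 1 count was worth 0.0767 to 0.104 CPM by library total. The biological coefficient of variation was 0.22. The design, the alternatives, 38 gene lists and the rule for named genes were fixed before the data were examined; the lists' direction test was replaced afterwards. That rule takes, among called genes with a symbol, a mean of 1 CPM or more and groups that do not overlap, the 10 largest rises and 10 largest falls for VPA (5 and 5 against lithium), the 5 smallest p-values where nothing is called, up to 4 members of each list by p, and 18 fixed genes such as Tph2 and Slc6a4, of which 0 had a name in the tables. Other named genes are marked as chosen after their values were seen, and some genes that the rule takes are not reported here.

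Gene symbols came only from the authors' tables, which pair 1384 identifiers with names, 1314 of them symbols; the gene table supplied with the data held 0 Ensembl identifiers. Because only genes that the authors listed by their p-values on these samples carry names, the planned camera test of lists against other genes, camera with an estimated correlation and fry were void and not run. In their place, Fisher's exact test (two-sided, SciPy 1.17.1) compared a list's rises and falls with those of all called genes with a symbol, for lists with at least 5 called members, with Benjamini-Hochberg adjustment (11 lists for VPA against control, 8 for VPA against lithium). It treats genes as independent, which they are not, and takes no account of expression level, with which the share of rises among calls changed. Mcpt8l2, Akr1c3, Ifit1, Ifitm3, Gstp1, Mgst2 and the histone genes belong to families of near-identical copies that can share reads, so their values are uncertain.

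Same-numbered control and VPA libraries deviated from their group means together (correlations 0.6, 0.533 and 0.525). This was measured over 10288 genes with a mean of 5 CPM or more. Their title numbers, the source of the pairing, were therefore taken as pairs in a blocked fit, though the labels state no pairing. Lithium 1 and 2 did not pair with the same-numbered controls in that check (-0.418 and -0.0815). The main fit was planned without the block, so its p-values and the fits without 1 library take no account of the pairs. The blocked fit is given where it changes the call of a list or moves a count by over 1.5 times. Alternatives were DESeq2 1.42.0, median-ratio, upper-quartile and total scaling, no filter, a filter of 1 CPM in 3 libraries, the replicate block, a non-robust fit, a test against a fold of 1.2, fits of only the groups compared, and leaving out each library; a block with VPA and control only and 2 surrogate variables (sva 3.50.0) were added after the data were seen. The scripts were tested on simulated data, 10 draws with 200 changed genes among 12719. For VPA against control 6.12% of 1.5-fold, 40.7% of 2-fold and 88.9% of 4-fold changes were called, and 6.05% of calls fell on unchanged genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.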

Results

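Polyadenylated RNA of RN46A cells, an immortalised rat raphe line with serotonergic features, was sequenced without strand information in 9 libraries, 3 in each of 3 groups. The cells were kept at 33 °C in 5% serum, differentiated for 72 h at 39 °C in 1% serum, and cultured for a further 72 h with 0.5 mM lithium, with 0.5 mM sodium valproate (VPA) or as controls. Lithium and VPA are both mood stabilisers; lithium inhibits glycogen synthase kinase 3 and inositol monophosphatase, and VPA inhibits histone deacetylases. The comparisons ask how each drug alters transcript levels in these cells. Reads assigned to genes numbered 10825133, 9580591 and 11555704 in control libraries 1, 2 and 3, 11743876, 11207844 and 13030300 in the lithium libraries, and 12129108, 9658054 and 12243806 in the VPA libraries. Of 32662 genes in the count table, 12719 had enough counts to be tested. Libraries of 1 group differed by more than counting noise, with a chi-square per degree of freedom of 28.8 to 73.1 for each pair, so no pair looked like repeated deposits of 1 library. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Names were held for 1384 Ensembl identifiers, 1314 of them gene symbols, those listed in the authors' deposited tables of comparisons; other genes entered the counts of calls but were not analysed here by name. Members of gene lists are counted below where they had a name and enough counts to be tested. The authors chose the genes they listed by p-value on these samples, so such counts are not shares of whole lists. In whole, the interferon list held 40 genes, the matrix list 51 and the serotonergic list 34.

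VPA against control asks which transcripts the drug altered. Igf2, a fetal growth factor (ENSRNOG00000020369), rose from 0.126 ± 0.0488 CPM in control to 11.6 ± 0.892 CPM with VPA (SD, n = 3), a log2 fold change of 6.39 ± 0.45 (SE). By library total, 1 count was worth 0.0865 to 0.104 CPM in the controls. The control level of Igf2, and with it the size of the fold change, therefore rests on few counts. The authors' deposited table places Igf2 on chromosome 1 from 215828101 to 215846911; the build of these positions, and whether starts count from 0 or 1, are not given in the sources used here. Vgf, a neuropeptide precursor induced by nerve growth factor, rose from 2.86 ± 2.07 to 54.2 ± 18.9 CPM. Col3a1, a fibrillar collagen (chromosome 9, 52023294 to 52059217 in the authors' deposited table), fell from 177 ± 92.9 to 22.6 ± 5.98 CPM. Lsp1, an actin-binding protein of leucocytes, fell from 16.2 ± 1.54 to 1.88 ± 1.06 CPM. Altogether 726 genes rose and 380 fell among the 12719 tested. Of these, 577 of the rises and 201 of the falls were 2-fold or more.

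The genes ranked next had a symbol, a call, a mean of 1 CPM or more over the 9 libraries and groups that did not overlap. These limits leave out Ccnd2, Sox10 and Lum, which are described below. Among the genes within them the 10 largest rises, on the log2 scale with SE, were Igf2, the nicotinic receptor subunit Chrna5 (5.09 ± 0.53), Lzts1 (5.06 ± 0.62), Tmeff1 (5.05 ± 0.57), the postsynaptic calmodulin-binding protein Nrgn (4.46 ± 0.60), Nxph4 of the neurexin-binding neurexophilins (4.36 ± 0.53), Vgf (4.22 ± 0.44), the potassium channel Kcnh3 (3.85 ± 0.62), the actin-bundling protein Lcp1 (3.75 ± 0.54) and Agap2. Agap2 had 1 count in all controls together against 180 with VPA, a ratio of 164 with a 95% counting interval of 29.0 to 6504. Within the same limits the 10 largest falls were the proteoglycan Dcn (-5.59 ± 1.18), Fam25a (-3.89 ± 0.51), Olfm3 (-3.88 ± 0.69), the cytokine receptor subunit Il20rb (-3.66 ± 0.39), Lsp1 (-3.15 ± 0.33), Mcpt8l2 (-3.04 ± 0.63), Col3a1 (-2.97 ± 0.37), the ephrin receptor Epha10 (-2.95 ± 0.64), Smim22 (-2.78 ± 0.56) and Prelp. Prelp, a second matrix proteoglycan, had 2 counts with VPA against 75 in control, a ratio of 0.0243 (counting interval 0.00288 to 0.0908). Such intervals, and floors elsewhere, cover counting error only.

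Adjusted p-values of these 20 genes ran from 5.98e-05 for Igf2 to 0.015 for Epha10 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Dcn was no longer called without VPA 1 (adjusted p = 0.0573 in edgeR's test), VPA 3 (0.0595) or control 2 (0.0597). By edgeR's adjusted p, neither was Epha10 without VPA 1 (0.0613) or VPA 3 (0.0618), nor Smim22 without VPA 1 (0.0514). Without control 3 the log2 changes were 6.25 for Lzts1, 4.46 for Tmeff1, 5.02 for Vgf and 4.75 for Kcnh3. Tmeff1 stood at 6.37 without control 2. Without control 1 they were 8.91 for Agap2, -4.80 for Dcn, -3.04 for Olfm3 and -4.17 for Prelp; without VPA 1, -7.71 for Prelp; without VPA 2, -3.66 for Epha10; and without VPA 3, -4.97 for Dcn, -3.67 for Mcpt8l2 and -3.50 for Smim22. Where 3 counts or fewer were left in a group, as for Agap2, Prelp, Lzts1 and Tmeff1, the fitted change depends on the prior count and is no bound.

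Of 14 pan-neuronal genes with a name and enough counts, 12 rose with VPA, 0 fell and 2 did not pass. The cell adhesion molecule L1cam changed by 2.96 ± 0.36, the neurofilament Nefm by 2.65 ± 0.35, the microtubule-binding tau gene Mapt by 2.56 ± 0.36 and the neuronal tubulin Tubb3 by 1.86 ± 0.27 (log2 ± SE). Of 11 genes of synaptic vesicles and transmitter release, 9 rose and 0 fell. The endocytic adaptor Snap91 went from 1.12 ± 0.402 to 11.7 ± 0.72 CPM and the calcium sensor Syt1 from 2.02 ± 0.628 to 12.2 ± 0.844 CPM. The active-zone protein Rims1 and the fusion protein Snap25 changed by 3.30 ± 0.48 and 3.19 ± 0.48. Of 8 voltage-gated channel genes 7 rose and 0 fell, among them Cacna1b of the N-type calcium channel (2.87 ± 0.32) and Cacna1h of a T-type calcium channel (1.80 ± 0.31). Of 11 adhesion and axon guidance genes 7 rose and 0 fell, among them Nrxn2 (3.67 ± 0.46) and Nfasc (2.70 ± 0.38). Adjusted over the list alone, 14, 10, 8 and 11 members of these lists passed. The named members were chosen by the authors on these samples, so none of these counts is independent evidence of direction or of the share that changed. In whole, the pan-neuronal, synaptic, channel and adhesion lists held 36, 40, 48 and 66 genes. Against the 621 rises and 336 falls among all called genes with a symbol, Fisher's exact test (two-sided, adjusted over 11 lists) gave adjusted p = 0.0579 for the pan-neuronal list, 0.0683 for the synaptic list and 0.142 for the channel and adhesion lists. With the replicate number as a block, 14 pan-neuronal and 10 synaptic genes rose and 0 fell, with adjusted p = 0.00677 and 0.0357 in Fisher's exact test. The lithium numbers in that block do not stand for pairs. With the block on VPA and control alone the same counts gave exact adjusted p = 0.00791 and 0.0496, the latter close to the threshold. The pan-neuronal list also passed without control 1 (Fisher's exact adjusted p = 0.0273), control 2 (0.0276), control 3 (0.0235), lithium 2 (0.0464), lithium 3 (0.048) or VPA 2 (0.0447), with DESeq2 (0.00697), upper-quartile scaling (0.0419), scaling by totals (0.0459) or no filter (0.019). Over all alternatives its adjusted p in Fisher's exact test ran from 0.00677 to 0.197. The synaptic list, at 0.0268 to 0.406 in the same exact test, also passed with DESeq2 (0.0413). In the adhesion list 1 gene fell without VPA 1, control 3 or lithium 3. With the block 9 adhesion genes rose and 2 fell, as they did with surrogate variables, and with DESeq2 or no filter, which test 12, 10 rose and 2 fell. With the block all 8 channel genes rose (Fisher's exact adjusted p = 0.0521).

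Growth factor signalling and serotonergic genes with a name were few. All 4 neurotrophic genes tested rose, among them Igf2, Vgf and the low-affinity neurotrophin receptor Ngfr (2.71 ± 0.23; from 4.45 ± 0.834 to 29.2 ± 4.59 CPM). Of 5 named serotonergic genes 4 rose and 1 fell. Maob, which degrades monoamines, changed by 2.60 ± 0.34, the serotonin receptor Htr5b by 2.98 ± 0.53 and the homeobox gene Hmx3 by 1.63 ± 0.31, and its neighbour Hmx2 by -0.83 ± 0.19. The monoamine transporter Slc29a4, named after its values were seen, changed by 1.05 ± 0.26. Slc29a4 lost its call without any 1 of VPA 1, VPA 2, VPA 3, control 1 or control 2 (adjusted p = 0.0641, 0.0769, 0.0884, 0.0995 and 0.0923, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The log2 change of Slc29a4 in these fits was 1.11, 1.06, 0.97, 0.92 and 0.87, in the same order. Hmx2 lost its call without VPA 1, VPA 2 or control 3 (edgeR adjusted p = 0.0806, 0.0723 and 0.0584). Vgf stood at 5.02 without control 3. The serotonergic list did not differ from the called genes at large (Fisher's exact adjusted p = 0.662), and adjusted over the list alone 4 neurotrophic and 5 serotonergic genes passed; the authors chose the named members on these samples, so neither count is independent evidence. Of 7 named genes often raised by histone deacetylase inhibitors 6 rose, among them the cell cycle inhibitor Cdkn1c (2.28 ± 0.30), and 1 fell, the keratin Krt8 (-1.73 ± 0.30, named after its values were seen; Fisher's exact adjusted p = 0.475; 7 adjusted over the list alone). The authors' deposited Cufflinks table lists 10 members of this list, 6 higher and 4 lower with VPA. Markers of neural crest and Schwann cells moved with these groups. Sox10, their transcription factor, had 90 counts with VPA against 3 in control, a ratio of 27.3 (counting interval 9.05 to 135), the neuregulin receptor Erbb3 rose by 2.28 ± 0.25 with Ngfr, and S100b fell by 1.28 ± 0.30. S100b lost its call without VPA 1, 2 or 3 or control 1 or 3 (edgeR adjusted p = 0.0526, 0.0738, 0.071, 0.0693 and 0.0506), and Sox10 had a fitted log2 change of 5.43 without control 3, which at so few counts depends on the prior count.

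Of 11 named genes of cholesterol synthesis 6 rose with VPA and 0 fell. The isopentenyl diphosphate isomerase Idi1 changed by 1.57 ± 0.26 and the sterol sensor Insig1 by 2.13 ± 0.40. Insig1 was at 197, 286 and 660 CPM in VPA 1, 2 and 3 against 74.2 to 108 CPM in the controls, and its change was 1.47 without VPA 3. All 11 passed adjusted over the list alone, which is not independent evidence, since the authors chose the names on these samples. The list's adjusted p in Fisher's exact test was 0.142, and 0.0289 with the replicate block, under which 11 rose, and 0.0413 with DESeq2 (0.0268 to 0.455 over all alternatives). With the block on VPA and control alone 11 rose as well (exact adjusted p = 0.0332). Only 3 rose without any 1 of VPA 2, VPA 3, control 1 or control 2. Of 5 named endoplasmic reticulum chaperone genes 4 rose, too few for a test of the list: Pdia4, a disulfide isomerase, by 1.29 ± 0.27, and Calr, Hyou1 and Sdf2l1. VPA 2 stood apart in all 4. Calr, the chaperone calreticulin, was at 1434, 3370 and 1495 CPM in VPA 1, 2 and 3, and at 899 to 957 CPM in the controls. Without VPA 2 the changes were 0.66 for Calr and 0.52 for Hyou1, neither called (adjusted p = 0.0853 and 0.168, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 1.72 for Sdf2l1. Only 2 of the 4 genes were called without VPA 2, control 1, control 2 or control 3. Hyou1 also lost its call without VPA 1 (edgeR adjusted p = 0.051) or lithium 1, 2 or 3 (0.063, 0.059 and 0.057). All 5 passed adjusted over the list alone, with the same limit.

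Interferon response genes fell. Of 19 members tested 12 fell, 1 rose and 6 did not pass. The antiviral effector Ifit1 went from 2.91 ± 0.17 to 0.541 ± 0.228 CPM and the membrane protein Ifitm3 from 11.4 ± 1.67 to 2.83 ± 0.792 CPM. The immunoproteasome subunit Psmb8 went from 80.9 ± 12.2 to 41.4 ± 3.53 CPM, and the transcription factor Irf1 from 92.6 ± 10.1 to 50.6 ± 2.82 CPM. The rise was that of the light chain of MHC class I, B2m (0.86 ± 0.20), named after its values were seen. This was the 1 list of 11 that differed in direction from the called genes at large (Fisher's exact adjusted p = 0.000301), and all 19 members passed adjusted over the list alone; the authors chose the names on these samples, so the counts are not independent evidence. The list was called under every alternative run, with 7 falls without VPA 1 or without VPA 2. With the replicate block 15 fell and 1 rose, and with that block on VPA and control alone 17 fell and 2 rose. B2m lost its call without VPA 2, VPA 3, control 1 or control 3 (adjusted p = 0.068, 0.0689, 0.0638 and 0.0527, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

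Of 19 extracellular matrix genes tested 9 fell with VPA, 4 rose and 6 did not pass. The falls held fibronectin, Fn1 (5080 ± 2133 to 1483 ± 379 CPM), the collagens Col3a1 and Col6a1 (-1.69 ± 0.26) and the protease Adamts1 (-1.99 ± 0.23). The rises were the basement membrane linkers Nid1 (1.31 ± 0.29) and Nid2 (1.10 ± 0.27), the gelatinase Mmp9 (2.41 ± 0.55) and the protease inhibitor Timp1 (1.08 ± 0.23), all 4 named after their values were seen. Of 9 named fibroblast and mesenchymal markers 5 fell and 1 rose. The matrix list also holds Col1a1, Col3a1 and Dcn, so the results of these lists are not separate. Col1a1 (-1.71 ± 0.34), Col3a1, Dcn, the calcium-binding S100a4 (2219 ± 1057 to 488 ± 152 CPM) and Lum fell, and the smooth muscle calponin Cnn1 rose by 2.32 ± 0.36. Lum, a collagen-binding proteoglycan named after its values were seen, had 0 counts in all 3 VPA libraries, where 3 counts would be 0.245 to 0.311 CPM, and was at 4.90, 1.41 and 0.533 CPM in controls 1, 2 and 3. The controls themselves varied, with Dcn at 21.4, 12.4 and 1.42 CPM and Col3a1 at 285, 123 and 124 CPM. Adjusted over the list alone 19 matrix and 8 fibroblast genes passed, again on names the authors chose from these samples.

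In Fisher's exact test the adjusted p was 0.0579 for the matrix list and 0.0613 for the fibroblast list, and with the replicate block 0.00677 (13 fell, 4 rose) and 0.0346 (6 fell, 1 rose). With that block on VPA and control alone the fibroblast list did not pass (exact adjusted p = 0.0678, 5 fell, 1 rose), nor with 2 surrogate variables (0.226), while the matrix list did (0.00791 and 0.0268). Both passed in the same exact test with DESeq2 (0.00749 for matrix, 0.0413 for fibroblast), upper-quartile scaling (0.0471 each), scaling by totals (0.0406 and 0.0459) and a test against a fold of 1.2 (0.0281 each), and the matrix list with no filter (0.019) and with the 2 groups alone (0.0195). Over all alternatives the exact adjusted p ran from 0.00251 to 0.0679 for the matrix list and from 0.0239 to 0.226 for the fibroblast list. These tests took no account of expression level either. The matrix list passed without control 1 (0.0135 in the same exact test), control 2 (0.00388), control 3 (0.007), lithium 2 (0.0464), lithium 3 (0.048), VPA 2 (0.00435) or VPA 3 (0.00251). The fibroblast list passed without control 3 (exact adjusted p = 0.0239), lithium 2 (0.0464), lithium 3 (0.048) or VPA 2 (0.0263). Without VPA 1 or VPA 3, 3 fibroblast markers fell, and without control 1, VPA 2 or VPA 3, 1 matrix gene rose. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment Lum was not called without control 1 (adjusted p = 0.106), VPA 1 (0.0905), VPA 2 (0.0793) or VPA 3 (0.0938), and Dcn not without control 2 (0.0597), VPA 1 (0.0573) or VPA 3 (0.0595). By the same adjusted p of edgeR's test, Nid1 not without VPA 3 (0.0602), Timp1 not without VPA 2 (0.0508) or control 1 (0.0514). Nor, by edgeR's adjusted p, was Mmp9 called without VPA 2 (0.0545), VPA 3 (0.0742), control 1 (0.0661) or control 3 (0.0548), or Nid2 without VPA 2 (0.0789), VPA 3 (0.0754), control 1 (0.0875) or control 2 (0.0756).

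Genes of Wnt signalling and of the pathway of the kinase that lithium inhibits went both ways with VPA. The genes of the kinase itself, Gsk3a and Gsk3b, had no name here and were not examined. The authors' deposited tables that gave the names did not list them under these symbols. Among the genes called here 110 had no name, so a missing name does not tell whether a gene was called. Of 8 tested targets of beta-catenin 3 rose and 1 fell. With the replicate block 3 rose and 3 fell, with that block on VPA and control alone 4 and 2, and with DESeq2 4 and 3. The transcription factor Lef1 rose by 1.83 ± 0.35, and the cyclin Ccnd2 had 72 counts with VPA against 2 in control, a ratio of 32.8 (counting interval 8.74 to 276). Of 6 named components of the GSK3 pathway 2 rose and 4 fell (Fisher's exact adjusted p = 0.235); the ligand Wnt11 changed by 2.32 ± 0.35. Fzd1, Akt1, Akt2 and Wnt10b made up the falls, the last 2 named after their values were seen, and 0, 0, 1, 1, 2 and 1 falls remained called without VPA 1, 2 and 3 and control 1, 2 and 3. Just 1 rise, that of Wnt11, remained without VPA 1, VPA 2, control 2 or control 3. Adjusted over the list alone 7 target genes and 6 components passed; the names were chosen by the authors on these samples, so the counts are no independent evidence. Without control 1 no control count of Ccnd2 was left, and its fitted log2 change of 7.56 depends on the prior count. Without lithium 1 or lithium 3, 2 target genes fell. The fall among the targets was Ccnd1, which was not called without VPA 1, 2 or 3, control 1 or 3 or lithium 2 (adjusted p = 0.0653, 0.112, 0.119, 0.0739, 0.0981 and 0.0535, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Among the rises, Nkd1 was not called without VPA 1, 2 or 3, control 1 or 2 or lithium 2 (edgeR adjusted p = 0.133, 0.074, 0.0908, 0.126, 0.116 and 0.0577) and stood at 2.16 without control 3.

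In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1106 genes. Among genes named above, edgeR's test with no low-count filter did not call Dcn (adjusted p = 0.114), Lum (0.212) or Sdf2l1 (0.0501), nor with 2 surrogate variables Lum (0.119), Calr (0.0592) or Hyou1 (0.105). By edgeR's adjusted p, Akt1, Akt2, Calr, Ccnd1, Hyou1, Nkd1, Slc29a4 and Wnt10b were not called with the 2 groups alone (0.0529 to 0.0711) or against a fold of 1.2 (0.0508 to 0.0881). With the replicate number as a block 1741 genes were called, 1105 of the 1106 among them with the same sign. Of the named genes 125 stayed the same with the block and 6 were stronger. With the block on VPA and control alone 119 stayed the same and 10 were stronger. The calls lost on leaving out a library come from fits without a block and with 1 library fewer. Without control 1, VPA 1, VPA 2 or VPA 3 the count was 694, 638, 698 or 669.

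**Figure D1:**
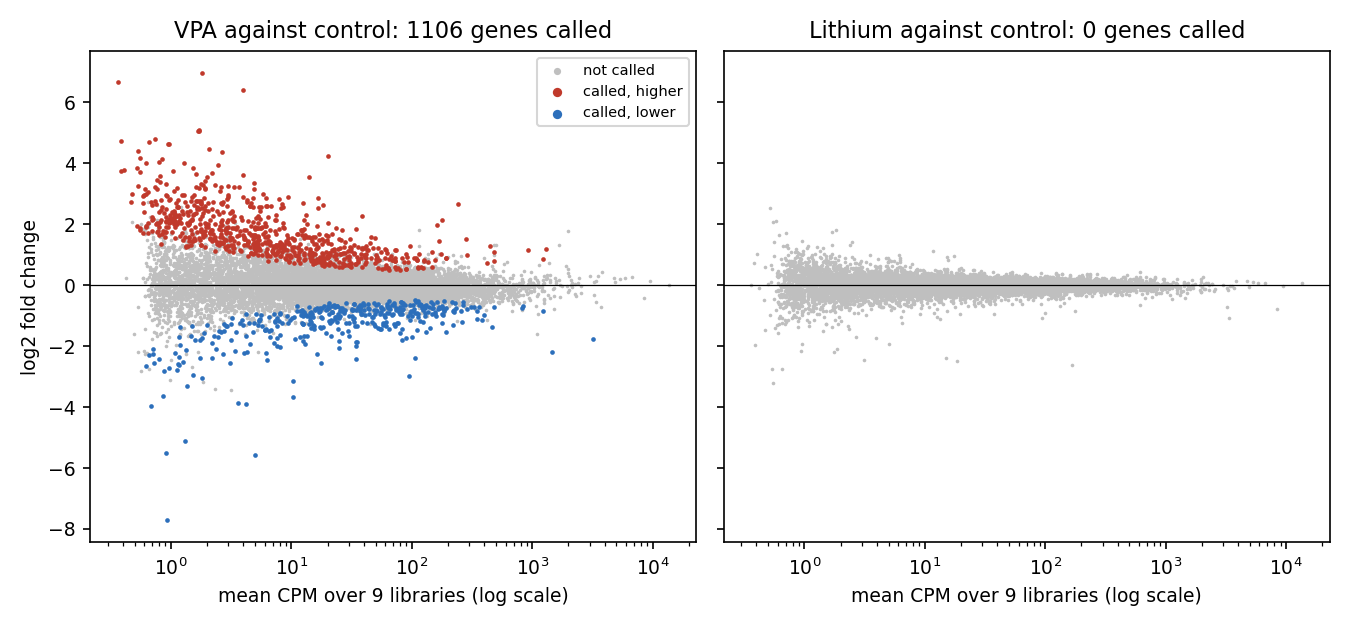
Log2 fold change of each of the 12719 tested genes against its mean CPM over the 9 libraries (log axis), for VPA (left) and lithium (right) against control; red and blue points are genes called higher or lower. VPA called 726 genes higher and 380 lower, and lithium called 0.

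**Figure D2:**
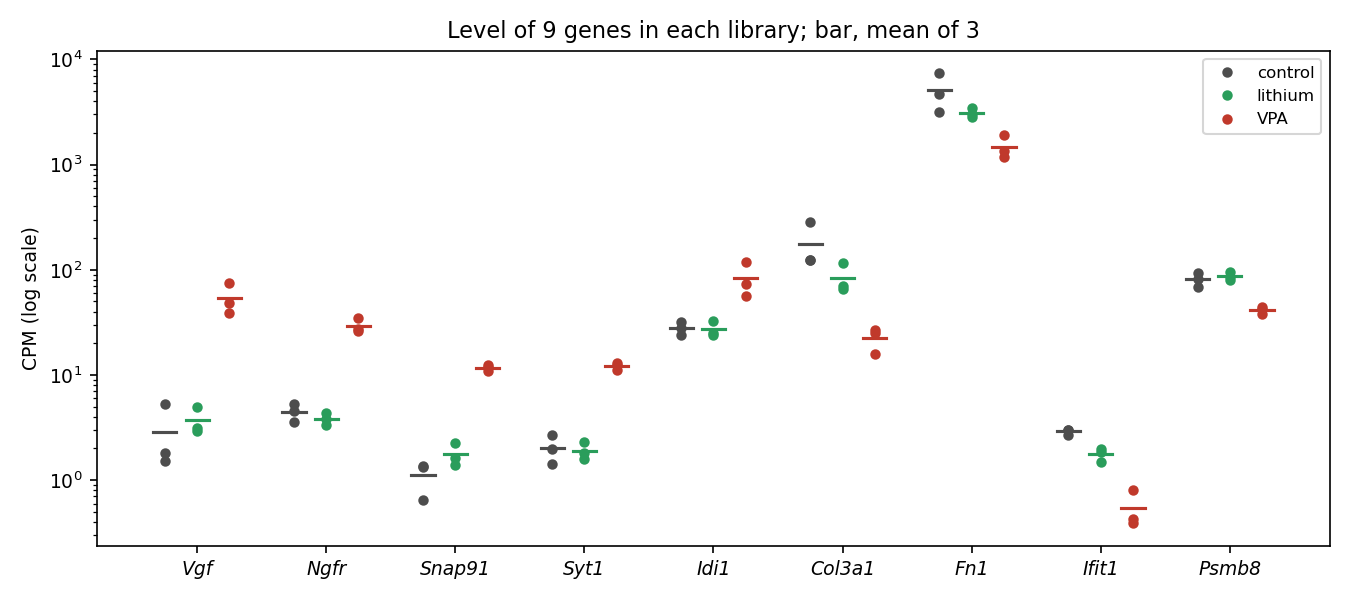
CPM (log axis) of 9 genes in each of the 3 control, 3 lithium and 3 VPA libraries, with a bar at each mean. The VPA libraries lie above all controls for Vgf, Ngfr, Snap91, Syt1 and Idi1 and below all controls for Col3a1, Fn1, Ifit1 and Psmb8.

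**Figure D3:**
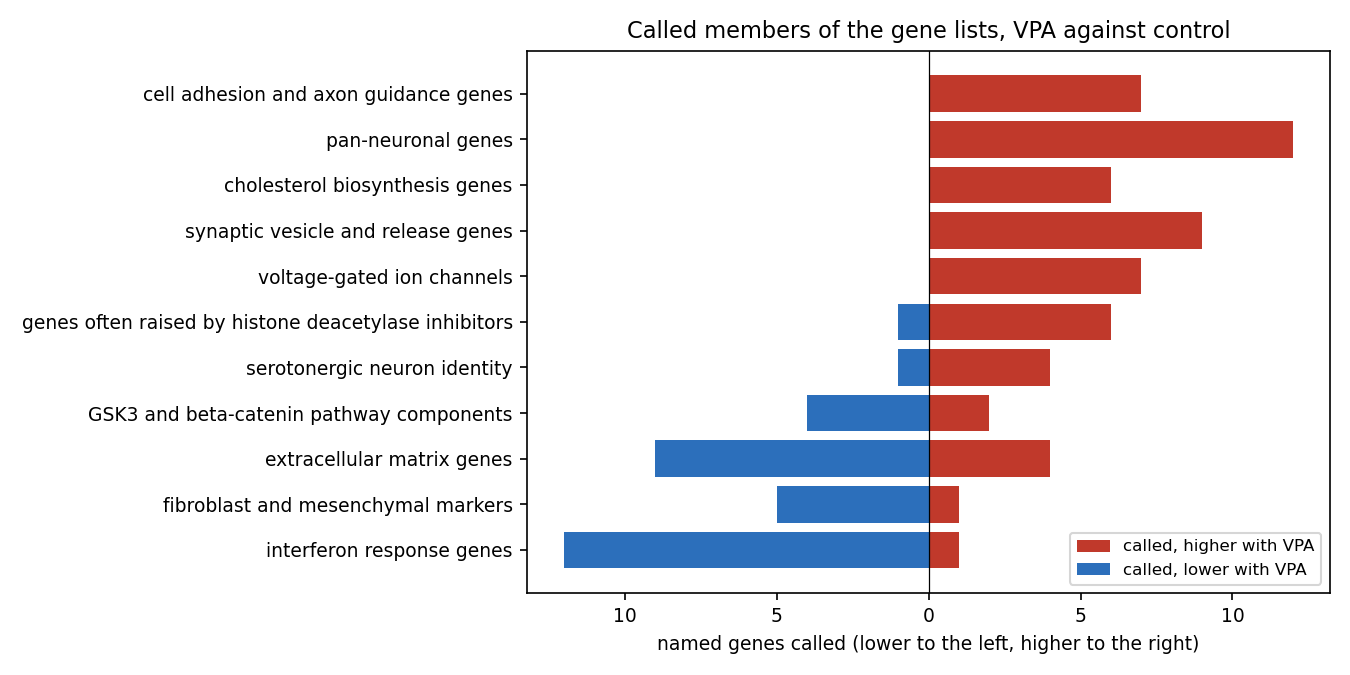
Number of named genes called higher (right, red) or lower (left, blue) with VPA against control in each of the 11 gene lists tested. The interferon list has 12 lower and 1 higher, and the pan-neuronal list 12 higher and 0 lower.

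Lithium against control asks the same of the other drug. No gene was called. Here edgeR's quasi-likelihood test called 0 of 12719 genes, with 116 at an unadjusted p under 0.05 where 5% of the genes would be 636; DESeq2 called 0, with 113 at an unadjusted p under 0.05. These fits take libraries as independent, whereas control and lithium libraries varied together (correlations of 0.801, 0.681 and 0.647), and no fit was blocked by these sets, which were read from the data. With 2 surrogate variables edgeR's test called 0, with 579 at an unadjusted p under 0.05. The smallest p-values among named genes belonged to Akr1c3, an aldo-keto reductase, at 1.65 ± 0.985 CPM with lithium and 5.35 ± 0.877 CPM in control (log2 -1.70 ± 0.38), Svop, a synaptic vesicle protein (1.30 ± 0.32), the immune checkpoint Vsir (-0.70 ± 0.19), Lrrc32 (-1.29 ± 0.35) and Nphs1 (1.45 ± 0.41). Each had an adjusted p of 1 in edgeR's test. No member of any list passed; the median log2 value was 0.02 for the 14 pan-neuronal genes, -0.03 for the 19 interferon genes, -0.42 for the 19 matrix genes and -0.76 for the 9 fibroblast markers. Adjusted over the list alone, 1 gene of the p53 list passed and 0 of the others. Most names came from the authors' tables of VPA against the same controls. Control values that were high or low by chance could therefore have moved the lithium medians as well. The medians and list counts thus do not measure an effect of lithium against control. In data simulated at these depths, 41.6% of genes changed 2-fold and 90.6% of genes changed 4-fold were called in this comparison, against 4.63% of those changed 1.5-fold, so changes of that size would mostly be missed. The simulated libraries were independent, unlike the real ones.

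VPA against lithium sets the drugs side by side. Among genes within the same limits of symbol, call, level and overlap, Igf2 was higher with VPA by 6.57 ± 0.45, and Agap2 (5.14 ± 0.60), Kcnh3 (5.11 ± 0.70), Nrgn (5.05 ± 0.62) and Nxph4 (4.19 ± 0.51) followed. The largest falls within these limits were Fam25a (-3.24 ± 0.51), Il20rb (-3.19 ± 0.39), Mcpt8l2 (-3.13 ± 0.62), Olfm3 (-3.10 ± 0.70) and Prelp, with 2 counts with VPA against 55 with lithium, a ratio of 0.0378 (counting interval 0.00447 to 0.143). Interferon genes again fell, 10 of 19 with 0 rises (Fisher's exact adjusted p = 3.8e-05; 17 adjusted over the list alone). Of 14 pan-neuronal genes 13 rose with 0 falls (Fisher's exact adjusted p = 0.053; 0.0174 with the replicate block; 0.0355 without control 2, 0.04 without control 3, 0.0214 with DESeq2, 0.0395 with no filter and 0.0316 with the 2 groups alone; 14 adjusted over the list alone), on names the authors chose from these samples. Without control 2 or control 3, 1 interferon gene rose. The synaptic list had 7 rises, and the channel, adhesion and cholesterol lists 6 each, all with 0 falls and an adjusted p of 0.249 in Fisher's exact test; 5 matrix genes rose and 4 fell (0.529). With the replicate block, whose lithium numbers do not stand for pairs, 11 cholesterol genes rose and 0 fell, and 5 matrix genes rose and 9 fell (exact adjusted p = 0.0585 each). In Fisher's exact test with 2 surrogate variables the adjusted p was 0.0301 for the cholesterol and synaptic lists (11 rises each), 0.0209 for the pan-neuronal list and 0.0658 for the matrix list (5 rose, 10 fell). Of 9 fibroblast markers 2 rose and 2 fell, and with the block 2 rose and 5 fell (exact adjusted p = 0.0807). In the same exact test, 6 genes often raised by deacetylase inhibitors rose and 1 fell (0.681). Cholesterol rises numbered 3 without lithium 1 or VPA 3 and 2 without lithium 2, and matrix rises 2 or 3 without lithium 1, lithium 2, VPA 1, VPA 2 or VPA 3. Matrix falls numbered 8 without control 2, and 0 of the last list fell without lithium 1. The direct comparison called 714 genes higher and 295 lower with VPA in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these 1009 genes, 590 rises and 235 falls were also called against control and 0 had the opposite sign. Independent lists of these sizes would share 40.8 and 8.81, but both comparisons use the same VPA libraries, so the lists are not independent. Simulated unchanged groups that share the VPA libraries shared at most 1. Almost no gene is called in such groups, so that value was set in advance. The overlap is therefore not a second test of the calls.

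The replicate block raised the count of called genes to 1609, and without lithium 1, lithium 2, VPA 1, VPA 2 or VPA 3 it was 553, 544, 638, 659 or 639. Olfm3 was no longer called without VPA 1, 2 or 3 or lithium 1 (adjusted p = 0.076, 0.0634, 0.0611 and 0.0689), nor Prelp without VPA 2, VPA 3, lithium 1 or lithium 2 (0.0681, 0.0826, 0.0635 and 0.0575), in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The fitted log2 change, which depends on the prior count for Agap2 and Prelp with so few counts left, was 6.68 for Agap2 without lithium 1, 5.90 for Nrgn without lithium 3, -3.76 for Mcpt8l2 without VPA 3 and -7.13 for Prelp without VPA 1.

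The 2 drugs were compared through their fold changes against the same 3 controls. No gene was called in both; 0 lithium genes were called by either tool. Across the 12719 genes, which are not independent replicates, the covariance of the log2 fold changes was 0.0361 and Pearson's r 0.222, and 57.6% of genes had the same sign. Unchanged groups simulated against shared controls gave a covariance of 0.0488 (range 0.0445 to 0.0548 over 100 draws), r = 0.506 and 66.8%, so the observed covariance lay 0.0126 below the simulated mean. The simulated libraries were independent, whereas real libraries of different groups varied together (control 3 and lithium 3 with a correlation of 0.801), which also alters this covariance, so the difference does not measure a shared effect. Without control 1, 2 or 3 the covariance was 0.0854, 0.083 or 0.0987, and without lithium 1 or lithium 3 it was 0.0614 or 0.0194. The 3 controls could not be divided into parts of at least 2 libraries, so the share of the covariance that comes from the controls was not measured apart.

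The authors' deposited tables list their own calls. Of 1212 genes in the authors' deposited DESeq2 table for VPA, 766 were higher and 446 lower. Of them 1164 were tested here, all 1164 with the same sign, and 983 of them (84.5%) were called. The authors' deposited Salmon and sleuth table lists 941 transcripts of 925 genes, of which 902 were tested, 899 had the same sign and 795 were called. In the authors' deposited Cufflinks table, 637 genes were higher and 460 lower with VPA, with Igf2 at 7.20 FPKM against 0.0405 FPKM in control and Col3a1 at 4.04 against 39.8 FPKM. By list, the authors' deposited Cufflinks table holds 12 pan-neuronal and 13 cholesterol genes, all higher with VPA, 2 interferon genes higher and 13 lower, and 4 matrix genes higher and 13 lower. It holds 5 adhesion genes higher and 2 lower, 3 serotonergic genes higher and 2 lower, and 3 targets of beta-catenin higher and 3 lower. Its 7 endoplasmic reticulum chaperone genes were all higher, and its 8 targets of the transcription factor ATF4 all lower. All 561 symbols found in the 3 tables had 1 sign in all of them, 355 higher and 206 lower. For lithium, the authors' deposited table lists 44 genes as higher and 93 as lower, at unadjusted p-values from 8.83e-05 to 0.0499 and an adjusted p of 0.9999 in DESeq2. Of these, 117 were tested here, all with the same sign and 0 called by edgeR's quasi-likelihood test, where 116 of all 12719 genes had an unadjusted p under 0.05. All these tables come from the same libraries, so the shared signs compare processing, not samples.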

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

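The replicate block with VPA and control alone, the fit with 2 surrogate variables and, for lists, Fisher's exact test and all fits but the block, the strict filter, scaling by totals and leaving out libraries were tests chosen after the results were seen; the other alternatives were planned. The 1106 genes of VPA against control ranged from 771 to 1533 under the scalings, filters, DESeq2, the non-robust fit, the fits of 2 groups and the test against a fold of 1.2, and rises made up 59.8 to 71.7% of them; they numbered 1741 with the replicate block, 2408 with the block on VPA and control alone and 4479 with surrogate variables (61.7, 58.6 and 53.1% rises), and 638 to 1026 on leaving out each library. VPA against lithium (1009) gave 1609 with the block, 4367 with surrogate variables and 544 to 1197 on leaving out each library. The cause of the lower and higher counts was not tested. Lithium against control gave 0 under every alternative run, with 113 genes at an unadjusted p under 0.05 in DESeq2, 221 with the block and 579 with surrogate variables. Of the lists, 1 was called for VPA against control, 4 with scaling by totals or upper-quartile factors, 6 with the block or DESeq2, 3 with no filter or a fold of 1.2, 2 with the 2 groups alone, 5 with the block on VPA and control alone, 5 with surrogate variables and 1 to 4 on leaving out each library; for VPA against lithium 1 was called, 2 with the block, DESeq2, no filter or the 2 groups alone, 4 with surrogate variables and 1 to 2 on leaving out each library, and the cause was not tested. Camera with a preset or an estimated correlation and fry were not run, since only genes the authors selected by p-value on these samples carry names. The covariance of the drugs' fold changes (0.0361) was 0.0376 with the block and 0.0194 to 0.0987 on leaving out each library, highest without a control. Fewer shared controls add more covariance by construction, but whether that accounts for the whole rise was not tested. The share of the authors' VPA genes with the same sign was 100% with DESeq2 and with the block. Ccng1, not called for VPA against control (log2 -0.01), turned to 0.0121 with upper-quartile factors and 0.0308 with totals, and lay between -0.12 and 0.17 on leaving out each library (0.0910 without control 2, 0.175 without VPA 3); the cause was not tested. Over all alternatives, the 118 named genes called and 13 not called for VPA gave 2489 values on the same side, 201 weaker, 53 stronger and 4 of opposite sign; the 10 of VPA against lithium gave 191 and 8 weaker, and the 5 of lithium 100 and 0. Control and lithium numbers did not pair (correlations -0.418, -0.0815 and 0.801), nor lithium and VPA numbers (-0.181, 0.053 and 0.538), so beyond control and VPA the numbers do not stand for pairs; the block changed no other call of a list than those given. Depth limits the smallest changes: with 0.0767 to 0.104 CPM per count, genes such as Agap2, Sox10 and Prelp rest on 1 to 3 counts in 1 group.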

Other observations

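All tests of explanations in this part were chosen after the results were seen, except the split of called genes by mean level, whose outcome was not known when it was written. Among lists not described above, VPA against control called 3 of 3 named folate and one-carbon genes, with rises of the glycine decarboxylase Gldc (1.53 ± 0.23, log2 ± SE, n = 3) and the folate hydrolase Ggh (1.82 ± 0.29) and a fall of the mitochondrial Aldh1l2 (-1.20 ± 0.21). Aldh1l2 was also 1 of 3 falls among 4 named ATF4 targets, and the only one without VPA 3. In fat oxidation 2 of 4 genes rose, among them the acyl-CoA synthetase Acsl1 (1.21 ± 0.17), and 1 fell; 1 rose without VPA 2, VPA 3, control 1 or control 2, and 0 fell without VPA 1, VPA 3, control 1 or control 2. Of 3 inositol phosphate genes 2 rose, among them the phospholipase Plcg2 (1.95 ± 0.25), and the phosphatase Inpp5d fell by 2.00 ± 0.26; 1 rose without VPA 2, control 1 or control 2. The p53 target Perp (2.58 ± 0.27) was 1 of 2 rises among 4 named targets and the only one without VPA 1, VPA 2 or control 1, and 1 target fell without lithium 2 or with the replicate block. The replication helicase Mcm7 (-0.83 ± 0.15) was 1 of 2 cell cycle genes, both lower, and the only one without VPA 1, VPA 2, control 2 or control 3. All 4 named lysosome and autophagy genes rose, Gabarapl1 by 0.81 ± 0.16; 1 rose without VPA 2 or control 2, and 2 without VPA 1, VPA 3, control 1, lithium 2 or lithium 3. Of 5 cation transport genes 2 rose, among them the sodium pump subunit Atp1b2 (2.53 ± 0.26), the only one without control 1; 4 rose with the block. Adjusted over the list alone 3 folate, 4 ATF4, 4 fat oxidation, 3 inositol, 3 p53, 2 cell cycle, 4 lysosome and 5 cation transport genes passed, on names the authors chose from these samples.

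Other cell types and stress genes gave smaller lists. Of 3 transmission genes tested the glutamate transporters Slc1a1 (2.26 ± 0.30) and Slc17a7 (2.86 ± 0.42; 3.53 without control 3) rose and the receptor subunit Grin2d fell (-1.24 ± 0.26), which was not called without VPA 1 (edgeR adjusted p = 0.0504), where a gene outside these 3 was tested and rose. The macrophage gene Cd68 rose to 32.6 ± 8.99 CPM from 10.5 ± 3.24 CPM. The astrocyte gene Fgfr3 rose by 1.62 ± 0.29, and the other astrocyte gene, S100b, fell, though not without VPA 1, 2 or 3 or control 1 or 3. Of 3 oligodendrocyte genes 2 rose, 1 of them Sox10, the only one without VPA 3. Of 6 oxidative stress genes 2 rose and 2 fell, among them Mgst2 (-1.16 ± 0.23); 0 rose without VPA 2 or control 1, 1 rose without VPA 1, VPA 3 or control 2, and 1 fell without VPA 1, VPA 2, VPA 3 or control 2. Dusp2, a phosphatase, rose by 2.35 ± 0.45 and 1 other immediate early gene fell, with 0 falls without VPA 1, VPA 3, control 2 or control 3. Of 2 heat shock genes 1 rose (0 without VPA 1 or control 1; 1 fell with the block), the 1 named clock gene rose (0 without VPA 1, VPA 2, control 2 or control 3), and of 5 hypoxia genes 2 rose (1 without VPA 1 or control 2, 0 without VPA 2 or control 1). Hdac7 (-0.77 ± 0.24) and the histone genes Hist1h1c (-0.87 ± 0.26) and H3f3a (-0.73 ± 0.25) were not called; Hdac7 was called without control 2 or with the block, both histone genes with the block on VPA and control alone, both histone genes without control 3 and 1 of them without lithium 3. Adjusted over the list alone 3 transmission, 1 macrophage, 2 astrocyte, 3 oligodendrocyte, 5 oxidative stress, 2 immediate early, 2 heat shock, 1 clock, 4 hypoxia, 1 deacetylase and 2 histone genes passed, with the same limit. Endothelial, catecholaminergic, oxidative phosphorylation and ribosomal protein lists had 0 members whose identifier was paired with a name and were not tested here. The authors' deposited Cufflinks table, where genes carry no identifier, lists 1 ribosomal gene as lower with VPA, Rpl9, named after its values were seen.

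More genes rose than fell with VPA. Rises made up 65.1 to 70.1% of calls under 4 scalings between libraries, so the choice among these 4 did not account for the excess. The 4 scalings lie close together, with TMM factors of 0.962 to 1.06, so they cannot decide whether scaling is the cause. With the replicate block the share was 61.7%, and 58.6% with that block on VPA and control alone. With 2 surrogate variables it was 53.1% (2378 of 4479). Among the 369 called genes of highest mean CPM, 151 rose and 218 fell, a share of 40.9% (95% exact interval 35.9 to 46.1), against 71.5% of the 369 at middle levels and 84.5% of the 368 lowest. A candidate explanation is that rises from near 0 counts are easier to call, and the onset of silent genes could give the same values, so both stay open. Neither the histone deacetylase inhibition nor another action of VPA was tested as a cause.

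Libraries of different groups varied together in 3 sets, control 1 with VPA 1 and lithium 2, control 2 with VPA 2 and lithium 1, and the libraries numbered 3. The lowest correlation of deviations from group means within a set was 0.293 and the highest between sets 0.053. Leaving out the 1000 most variable genes left 0.365, so a few such genes did not account for the sets, whereas thinning to equal totals hardly moved the value (0.288), which is no test, and sequencing depth stays open. The labels give no date or batch, so a shared culture or handling day may be the source and stays open as well; no biological explanation was tested. The sets were read from the same values that show them, and the lithium titles number 2 of these libraries the other way round.

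The 6 libraries of each comparison were also split in other ways, with the remaining group kept in the fit. For VPA against control 1 of the 10 splits, the real one, called as many as 1106, and the highest other called 0. The lithium comparison called 0 in all 10, and VPA against lithium called 1009 in 1 of 10, with 0 as the highest other. Because 10 splits cannot give a share under 0.05, they are too few for that test.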
